A study of Manihot esculenta and Manihot esculenta subsp. peruviana with 18 samples.

How the data were processed

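Transcript levels were measured in shoots (stem and leaves) of cassava plantlets, Manihot esculenta, on 18 one-colour Agilent arrays. The labels name 3 cultivars, M TAI16, M ECU72 and M PER417-003, the last recorded as Manihot esculenta subsp. peruviana, each with 3 untreated and 3 drought-treated biological replicates. Per the labels' protocols, cut shoots grew for 4 weeks in bottles on MS medium with 2% sucrose and 0.3% gelrite under 16 h of light and 8 h of darkness. Drought meant lifting the plantlets out of the gelrite and leaving them on a plastic plate for 1 h at 30 °C, 50% relative humidity and 40 to 80 μmol photons per square metre and second. Total RNA was extracted with a plant RNA kit, and 0.5 μg of it was made into Cy3-labelled cRNA, per the labels.

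Per the file headers, all 18 arrays were read with Agilent Feature Extraction 9.1.3.1, with spatial and multiplicative detrending on and surrogate values in place of signals too close to background (6.96% to 10.7% of non-control spots per array). The header's background correction setting was 0, but the processed signal was background-subtracted. In each file a fitted spatial background, with a median of 38.6 to 47.5 units per array, had been taken from the spot's mean signal. The deposited scanner files hold the spot intensity on a linear scale, not normalized between arrays. Each array had 43044 non-control spots, which were 21522 probes of 60 bases printed 2 times each. Every probe stood for a contig or EST of its own, so no averaging over several probes of a transcript applied. The deposited value table is a linear ratio to the 75th percentile of each array, a unit found from the values. Its columns had 75th percentiles near 1 and medians from 0.167 to 0.220, and their log2 values correlated with those of the scanner files at r of 0.999 or more on every array. No label states how that table was made, and its background handling beyond the scanner's own stays unknown.

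The main values were log2 of the processed signal minus each array's 75th percentile over non-control spots. Control spots were left out, outlier-flagged spots were set to missing, and the 2 spots of a probe were averaged on the log2 scale. Probes well above background on all 3 arrays of at least 1 of the 6 groups were tested, which left 18664 probes. A linear model with 1 coefficient per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, Benjamini-Hochberg adjustment within each contrast). A probe counted as changed at an adjusted p under 0.05. The contrasts were drought minus untreated in each cultivar, their average, the differences between cultivars in that effect, and the differences between untreated cultivars. The groups came from the sample titles, and these choices, the alternatives and 27 gene lists were fixed before the data were examined.

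Gene lists were drawn by name from the descriptions in the array files, which are mostly best matches in Arabidopsis (12988 probes) or rice (3295 probes). For 4336 probes the description is Unknown. None of the probes' names matched the reference table of assembly M.esculenta_v8 (0 matches), so no genome positions are given and transcripts are named by probe and array description. A name such as NCED3 thus says which known gene the contig resembles. Drawing by name also let some genes of other kinds into lists, as given below. The lists covered abscisic acid, LEA proteins, osmolytes, heat shock, 6 transcription factor families, jasmonate, ethylene, redox, photosynthesis, cell walls, aquaporins, auxin, ribosomes, cell cycle, cyanogenesis, xylem, meristem, root transport, clock, cuticle, and calcium and kinase signalling. They were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, over the 18574 probes with no missing value. Lists with fewer than 3 measured members were not tested, which left 25 lists. The plan let only the brightest of a gene's probes stand for it, but this was not done for same-named contigs. Contigs with the same name, such as those of BAM1 and GOLS4, each counted as a member. A gene can thus count several times in the list tests and list counts.

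Transcripts were named by a fixed rule: per cultivar the 6 largest rises and 4 largest falls among changed probes whose drought and untreated arrays did not overlap, up to 3 per list with the smallest p in the average drought effect, and 3 in each direction for each difference between cultivars. The rule also took 10 rises and 6 falls among probes changed in all 3 cultivars, of which there were none. Same-named probes of separate contigs were kept apart. Transcripts taken from the fit on only the 6 M ECU72 arrays, and probes with no description, were chosen after their values were seen. Where a probe was not well above background on any array of the dimmer group, only a lower bound of the fold is given. It sets the brighter group's mean against, per array, the higher of the lowest signal well above background and the probe's own signal.

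Slide and array position came from the file headers, with slides numbered 1 to 6. Slides 1, 2 and 3 each held 1 untreated array (position 2) and 1 drought array (position 4) of M ECU72 with the same replicate number. Slides 4, 5 and 6 held the 12 other arrays at positions 1 to 4. The M ECU72 arrays were scanned in 1 session and the other 12 in another. The share of non-control spots well above background was 80.9% to 87.7% per array, and the 75th percentile of the signal ran from 1916 to 5191 units. The number of arrays, 3 per group, limits the precision.

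Alternatives were quantile or median scaling, normexp background correction with an offset of 50, the deposited value table, no filter or a filter on all 18 arrays, outlier spots kept, a trended robust prior, array weights, a fit on only the groups compared, a 2-fold minimum, the replicate number as a block, slide as a fixed or random block, and leaving out each array. The fit was tested on simulated data with the real probes, labelled groups and per-probe spread and 200 of 18570 probes changed in each of 5 draws. Simulated arrays varied independently, without any grouping by position. For the M ECU72 drought effect it found 29.4% of 2-fold and 73.8% of 4-fold changes, and 5.50% of its calls were false. For the M TAI16 effect it found 32.4% and 70.4%, with 3.57% of calls false, and for the M PER417-003 effect 30.4% and 71.8%, with 4.31% of calls false. The real arrays with these labels grouped by position, so the shares found do not carry over to them.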

Results

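The data describe the response of cassava shoots to 1 h of drying in 3 cultivars, with 3 untreated and 3 drought arrays per cultivar. The arrays carried 21522 probes, of which 18664 were measured well enough to test. Between 80.9% and 87.7% of the non-control spots on each array were well above background.

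The arrays of M ECU72 grouped by their labels on average, and the 12 arrays labelled M TAI16 and M PER417-003 did not. In M ECU72 all untreated arrays were at position 2 and all drought arrays at position 4, so label and position cannot be told apart there. Within the M ECU72 groups the mean Pearson correlation over probes was 0.974, against 0.956 between untreated and drought arrays. Untreated replicate 3 did not stand apart from the drought arrays. It correlated at 0.957 and 0.9696 with the other untreated arrays and at 0.9574, 0.9675 and 0.9652 with the drought arrays. Within the 4 labelled groups of the other cultivars the mean was 0.958, and each of the 12 arrays had its closest match outside its labelled group. The closest match was in all 12 cases an array at the same position of another slide. The mean correlation within positions was 0.989 (range 0.979 to 0.995), the highest of all 15400 ways to put the 12 arrays into 4 groups of 3 (exact permutation test, one-sided, p = 6.49e-05). The labelled groups ranked 12337 of 15400 in the same exact permutation test (p = 0.801). Position accounted for 77.4% of the variance among these 12 arrays and labelled group for 17.9%, where a random grouping gave a median of 26.0%. Directions drawn from the M TAI16 and M PER417-003 labels below are therefore those of arrays labelled so.

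**Figure D1:**
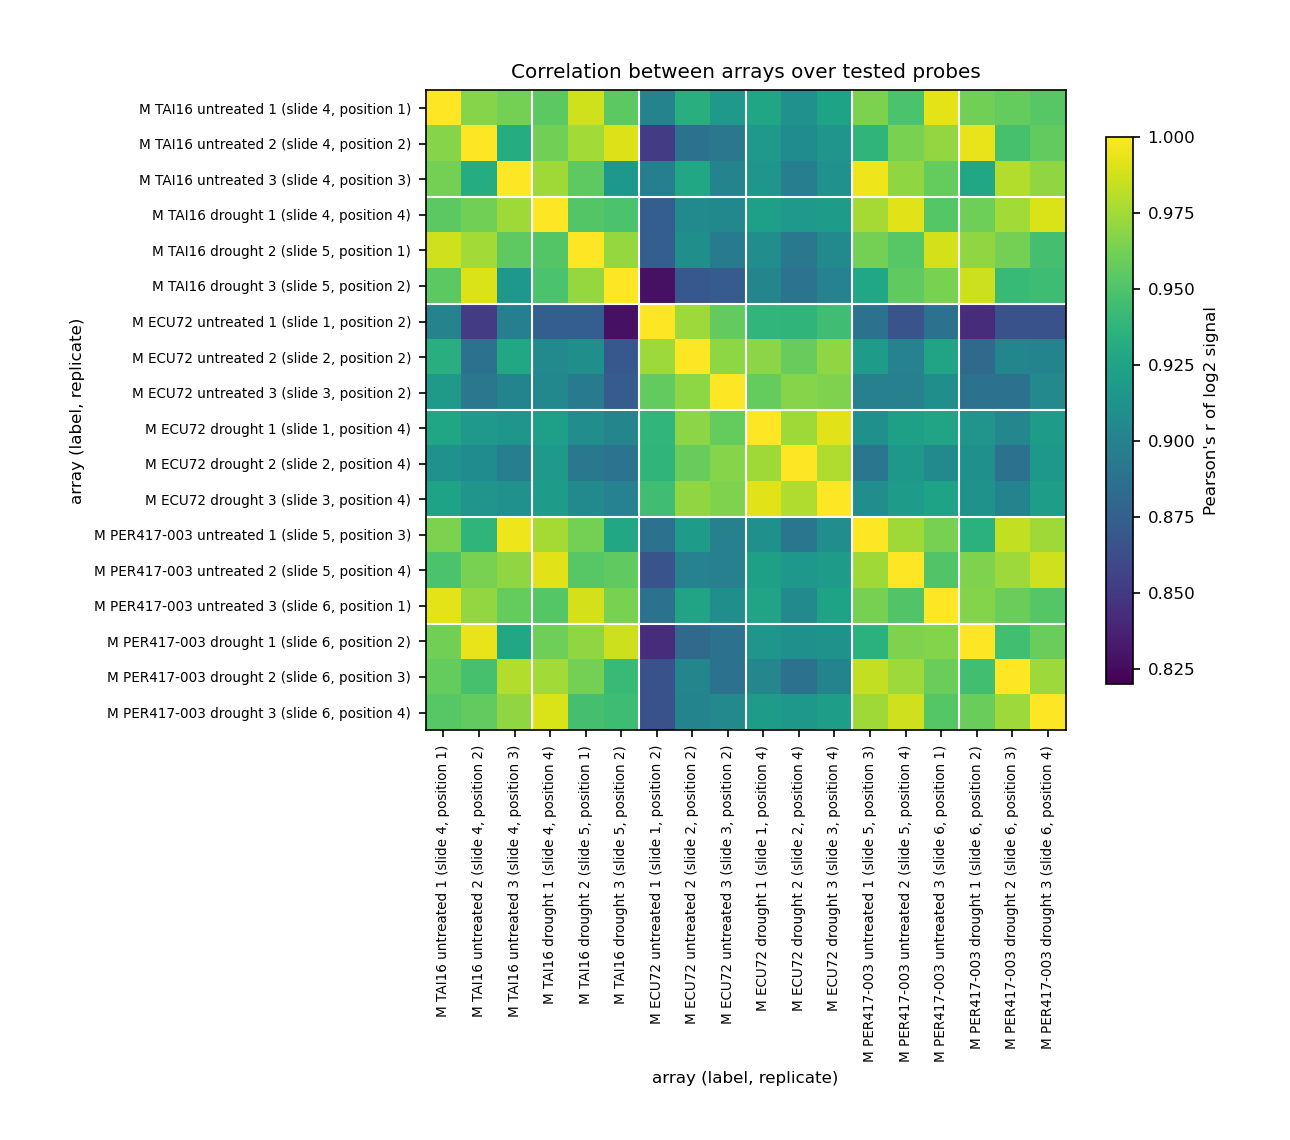
Pearson's r of log2 signal between all pairs of the 18 arrays over tested probes, in label order, with slide and position in each name and white lines between labelled groups. The M ECU72 arrays form 1 block, with a mean r of 0.901 to the other arrays, while the bright cells among the other 12 join arrays of the same position, with a mean r of 0.989.

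The first comparison asks which transcripts differed after drought in M ECU72. In the fit on all 18 arrays 47 probes rose and 148 fell, of which 42 and 126 changed at least 2-fold. Among the named rises were an aquaporin of the PIP1 type, a water channel of the plasma membrane (R_Mes01_001345, log2 change 3.73, SE 0.71, adjusted p = 0.0243), a pentatricopeptide repeat protein (R_Mes01_008820, 2.46, SE 0.28, adjusted p = 0.00151) and a putative epoxide hydrolase (R_Mes01_020421, 2.19, SE 0.48, adjusted p = 0.0441). A mitochondrial transcription termination factor (R_Mes01_009048) rose at least 2.37-fold and a leucine-rich repeat receptor kinase (R_Mes01_016265) at least 2.58-fold, both from untreated arrays not well above background. A fucosyltransferase, FT1 (R_Mes01_002556), rose by 2.85 on the log2 scale and was well above background on 1 of the 3 untreated arrays. Among the named falls was CUE1, which resembles the phosphoenolpyruvate transporter of the plastid envelope. Its probe R_Mes01_017414 was at least 3.72-fold lower after drought (adjusted p = 0.00151), with no drought array well above background. A BolA-like protein was at least 2.29-fold lower, the ubiquitin-conjugating variant MMZ1 at least 2.95-fold lower, and a leucine-rich repeat kinase (R_Mes01_016052) changed by -2.42 (SE 0.31, adjusted p = 0.00306). A probe with no description (R_Mes01_015276), singled out after its values were seen, rose at least 40.4-fold (adjusted p = 0.00194) from untreated arrays not well above background.

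The spread of the 18-array fit includes that of the arrays labelled M TAI16 and M PER417-003. In the fit on only the 6 M ECU72 arrays 188 probes rose and 473 fell, 121 of them shared with the 18-array calls. Among its rises, named after their values were seen, were 2 probes of NCED3, the 9-cis-epoxycarotenoid dioxygenase that opens the synthesis of abscisic acid. Probe R_Mes01_015228 differed by 8.17 on the log2 scale (SE 1.00, adjusted p = 0.0194), from -7.82 ± 1.90 to 0.35 ± 1.05 (SD, n = 3 each), with 1 of the 3 untreated arrays well above background. Its sequence is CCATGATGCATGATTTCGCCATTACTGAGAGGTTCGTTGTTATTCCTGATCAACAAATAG. Within slides 1, 2 and 3 its difference was 8.24, 10.61 and 5.66. Probe R_Mes01_010429 differed by 6.83 (SE 1.30, adjusted p = 0.0463), also with 1 such array. In the 18-array fit neither passed (adjusted p = 0.150 and 0.252).

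Further rises of the 6-array fit, also named after their values were seen, included single transcripts for a water channel, a protective protein and sugar enzymes. As a list, the osmolyte and raffinose sugar genes went both ways, as given below. The tonoplast aquaporin TIP1;3 (R_Mes01_013038, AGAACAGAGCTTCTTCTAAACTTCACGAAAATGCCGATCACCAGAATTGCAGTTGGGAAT) rose by 5.65 (SE 0.64, adjusted p = 0.0179), with within-slide differences of 7.31, 5.72 and 3.93. LEA14, a late embryogenesis abundant protein, rose by 4.84 (SE 0.86, adjusted p = 0.0390). Galactinol synthase GOLS1, which opens raffinose synthesis, rose by 4.47 (SE 0.51, adjusted p = 0.0182), and 3 probes of the starch-degrading beta-amylase BAM1 rose by 2.71 to 3.12. Transcription factors among the rises included an AP2 domain factor (at least 10.3-fold), ANAC071 (4.37, with 2 of the 3 untreated arrays well above background) and ERF9 (R_Mes01_000892 at 3.21 and R_Mes01_012546 at 3.54). The gibberellin-inactivating GA2OX2 rose by 4.32, the kinase MAPKKK17 by 4.29 (1 of the 3 untreated arrays well above background) and a protein kinase (R_Mes01_010032) at least 14.5-fold. The light-harvesting protein LHCA4 (R_Mes01_008299) fell by 3.02 (SE 0.29, adjusted p = 0.0170), while another LHCA4 probe (R_Mes01_000229), at -0.65, did not pass (adjusted p = 0.161). LHCB5 (R_Mes01_000522), also light-harvesting, rose by 0.85 (SE 0.16, adjusted p = 0.0466). Of these, LEA14, GOLS1, TIP1;3, BAM1, the AP2 factor, ANAC071, ERF9, GA2OX2, MAPKKK17, the protein kinase, LHCB5 and the fallen LHCA4 probe had adjusted p values between 0.0617 and 0.384 in the 18-array fit.

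**Figure D2:**
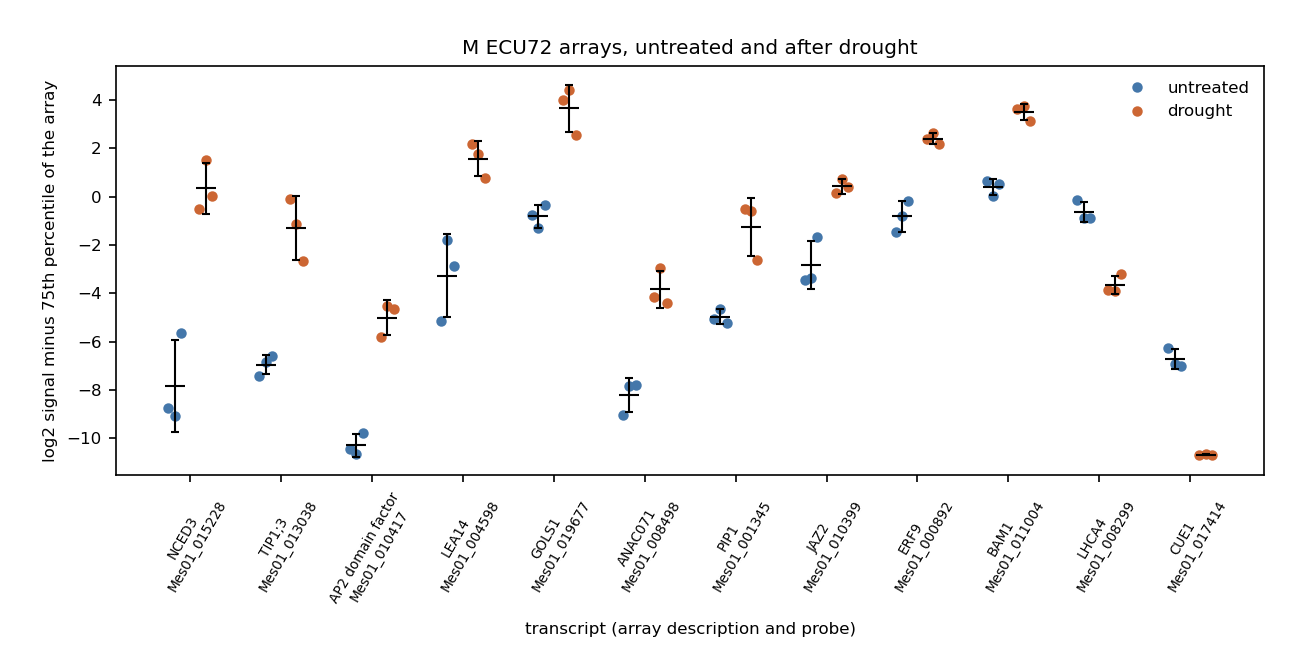
Log2 signal minus the array's 75th percentile for 12 named transcripts on the M ECU72 arrays, each point 1 array and each black mark the mean with its SD (n = 3). No drought point overlaps an untreated point of the same probe, but the untreated points of the AP2 factor and the drought points of CUE1 were not well above background, so only lower bounds of 10.3-fold and 3.72-fold hold for them.

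By list, jasmonate, LEA and dehydrin, aquaporin, cell wall loosening and DREB and ERF genes shifted up in M ECU72 by camera with a preset correlation, but none of the list calls held with an estimated correlation, where these 5 lists had adjusted p = 0.542, 0.478, 0.316, 0.478 and 0.542 in that order. The 28 jasmonate probes had a median of 1.04 (camera adjusted p = 0.000813), with 21 above 0. JAZ repressors led it: JAZ2 (R_Mes01_010399) at 3.26 and 2 JAZ1 probes at 3.47 and 2.25 passed the 6-array fit. In the 18-array fit no member passed over all probes, and 0 passed adjusted over the list alone. The 23 LEA and dehydrin probes had a median of 0.96 (adjusted p = 5.56e-05), with 0 past the threshold over all probes, and 4 higher and 1 lower adjusted over the list alone. The list was drawn by name and also took genes called early responsive to dehydration, among them ERD15 and the heat shock protein HSP81-2. Its shift is therefore not one of LEA proteins and dehydrins alone. Of ERD15, R_Mes01_011729 rose by 1.96 in the 6-array fit (SE 0.26, adjusted p = 0.0199). The 26 aquaporin probes had a median of 0.44 (adjusted p = 2.90e-07), with 1 higher over all probes and 8 higher and 0 lower over the list alone. The 73 cell wall loosening probes had a median of 0.54 (adjusted p = 1.45e-06), with 0 past the threshold over all probes and 3 higher over the list alone; the xyloglucan endotransglycosylases XTR3 (2.85) and XTR6 (3.19) passed the 6-array fit. The list of DREB and ERF factors had a median of 0.38 in 30 probes (adjusted p = 0.00230), with 0 past the threshold over all probes and 0 adjusted over the list alone.

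Of 6 further lists that passed camera, none held with an estimated correlation (adjusted p between 0.478 and 0.658). The shift was positive for the cell cycle and histone list (median 0.39, 16 probes, adjusted p = 0.000813), the ribosome list (0.24, 295 probes, adjusted p = 2.00e-07), the cuticle list (0.48, 9 probes, adjusted p = 0.0145) and the list of secondary wall and xylem genes, which marks stem tissue (0.37, 30 probes, adjusted p = 0.00184). Photosynthesis (median -0.21, 144 probes, adjusted p = 0.00130) and the circadian clock (-0.47, 17 probes, adjusted p = 0.0127) shifted down, the latter with LHY at -1.84 and PRR5 at -1.21, neither past the threshold. Over all probes 2 ribosome members fell, among them ARP1 (-2.25, adjusted p = 0.0364, 1 of the 3 drought arrays well above background), and 1 photosynthesis member, the Rubisco small subunit R_Mes01_005220 (-0.76, adjusted p = 0.0445); no member of the other 4 lists passed. Counted adjusted over the list alone, 3 cell cycle members were higher, 2 ribosome and 2 clock members were lower, and 0 passed in the cuticle, xylem and photosynthesis lists. In fry on the 6 arrays LEA and dehydrin (adjusted p = 0.0305), DREB and ERF (0.0249), HD-Zip factors (0.0305, downward) and the clock (0.0347, downward) passed; fry tests whether a list's genes move, on balance, one way, and does not compare them with other genes. In the 18-array fit fry passed for no list, with adjusted p = 0.178, 0.243, 0.211 and 0.178 for these 4. Within slides 1, 2 and 3 the jasmonate median was 1.03, 1.38 and 0.59, the DREB and ERF median 0.53, 0.61 and 0.66, and the LEA median 0.91, 0.41 and 0.50. The cell wall median was 1.74, -0.29 and 0.49, the cell cycle median 0.61, -0.20 and 0.41 and the cuticle median 0.78, -0.089 and 0.67, all moving with the xylem median of 1.05, -0.44 and 0.50. The photosynthesis median was -0.40, -0.32 and 0.042, so these 5 lists did not keep 1 direction over the slides.

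**Figure D3:**
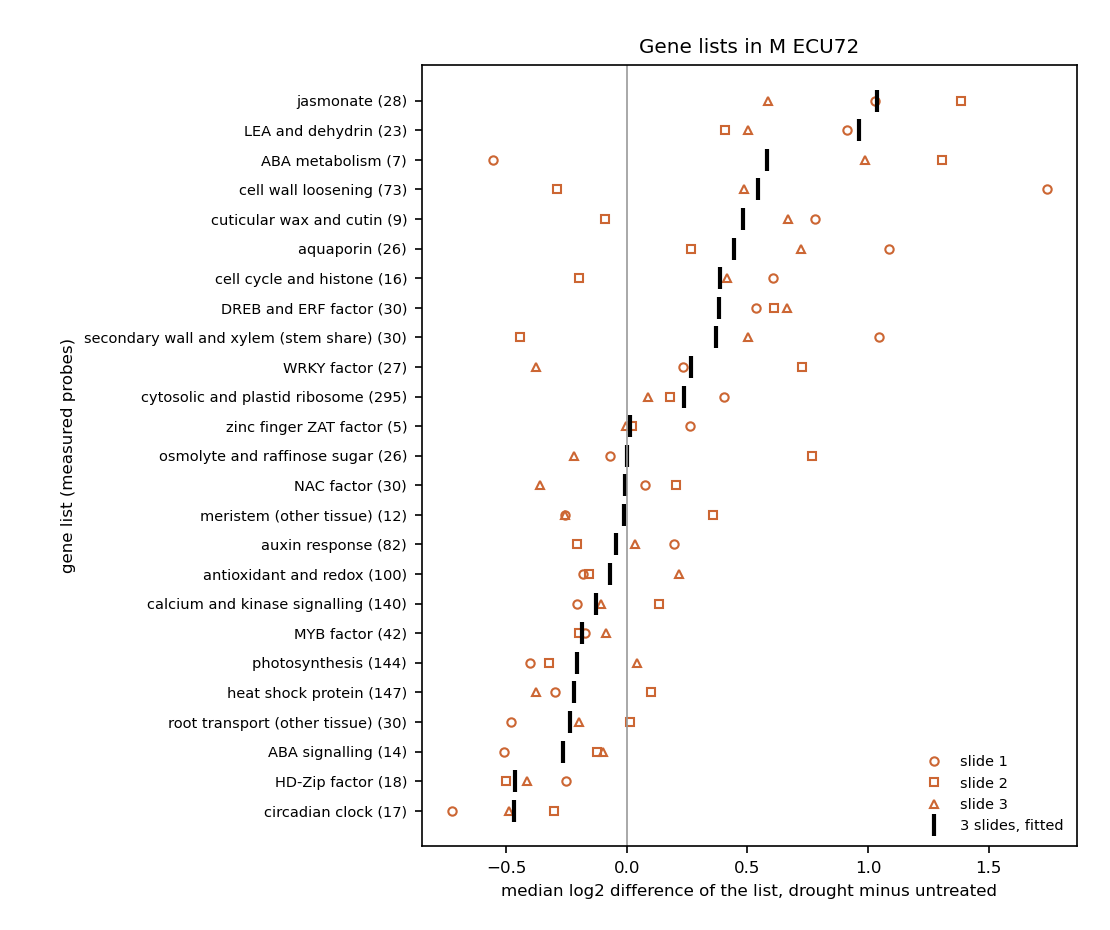
Median log2 difference between drought and untreated M ECU72 arrays for each list with 3 or more measured probes, with 1 open symbol per slide and a bar for the fit over the 3 slides; probe numbers are in brackets. The jasmonate, LEA, aquaporin, ribosome and DREB and ERF symbols lie above 0 on all 3 slides, and the clock, HD-Zip, MYB and ABA signalling symbols below 0.

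ABA metabolism (median 0.58, 7 probes, adjusted p = 0.251) did not pass in spite of the 2 NCED3 probes, and its mean was 2.13. NCED4, a carotenoid cleavage relative, was at -1.48 (adjusted p = 0.165). ABA signalling had a median of -0.26 (14 probes, adjusted p = 0.238). Osmolyte and raffinose sugar genes went both ways (median -0.00058, 26 probes), with 0 higher and 6 lower adjusted over the list alone in the 18-array fit and 5 higher and 0 lower in the 6-array fit, while 3 GOLS4 probes were at -1.34 to -1.70. In the 18-array fit the heat shock list (147 probes, median -0.22, adjusted p = 0.238) held 1 higher and 2 lower probes, and 1 of its fallen members was a DNAJ co-chaperone (R_Mes01_010491, -1.23, adjusted p = 0.0358). NAC (-0.0059), WRKY (0.27), MYB (-0.19), HD-Zip (-0.46), zinc finger (0.013), auxin (-0.046), redox (-0.071), meristem (-0.014), root transport (-0.24) and calcium and kinase (-0.13) lists did not pass either. The zinc finger list also took probes of the zinc transporter MTP1, by its other name ZAT1, so its median is not that of zinc finger factors alone. Likewise the redox list took OCP3 by the word peroxidase in its name. For the osmolyte, NAC, auxin, meristem and calcium lists the median was below 0 and the mean above it, and for redox and root transport the test pointed up with median and mean below 0. Over the list alone, 2 NAC, 2 WRKY, 2 meristem, 1 HD-Zip and 1 calcium and kinase members were higher and 1, 0, 0, 3 and 1 lower, and 2 MYB members were lower. Counted the same way, 2 heat shock members were higher and 4 lower, 1 ABA metabolism member was higher and 1 lower, and 0 passed in the ABA signalling, zinc finger, auxin, redox and root transport lists. Ethylene synthesis (1 probe, ACO1, -0.89) and cyanogenesis (2 probes, median -0.14) were too small to test. Within the failing lists the NAC factor NAC2 (1.55, adjusted p = 0.0152), the meristem factor KNAT1 (2.15, adjusted p = 0.0125) and the calcium-sensor kinase CIPK9 (-1.29, adjusted p = 0.0445) changed in the 18-array fit, NAC2 and KNAT1 with 1 of the 3 untreated arrays well above background. An HD-Zip factor (R_Mes01_020734), named after its values were seen, was at least 1.20-fold higher (adjusted p = 0.0226), against the downward median of its list.

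In M ECU72 the replicate number is also the slide, with 1 untreated and 1 drought array on each. The count of changed M ECU72 probes was 0 with the replicate number as a block, 60 with slide as a fixed block and 138 with slide as a random block. Both fixed blocks make the same pairs in M ECU72, so 0 against 60 comes from how the other cultivars' arrays were blocked. In the fit on only the 6 M ECU72 arrays the count was 0 with that replicate block, an alternative added after the results were seen, so none of the calls of that fit, NCED3, TIP1;3 and GOLS1 included, held with it. With 3 blocks for 6 arrays little is left to estimate the spread, so this 0 does not show that the differences were absent. The spread from array positions, also added later and with groups chosen from the grouping itself, gave 3294 with the replicate block. In the 18-array fit without a block the count was 36 without drought replicate 3, 37 without untreated replicate 1, 58 without drought replicate 1, 111 without untreated replicate 3 and 295 without drought replicate 2. Without untreated replicate 2 it was 215, with 114 higher and 101 lower, so the excess of falls did not hold there.

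In the arrays labelled M TAI16, no probe passed the limma test after drought (0 higher, 0 lower, with 607 at an unadjusted p under 0.05), and the NCED3 probes differed by 3.58 and 3.59 (SE 2.69 and 2.96, adjusted p = 0.955 for both). The untreated arrays lay at positions 1, 2 and 3 and the drought arrays at positions 4, 1 and 2. Positions 1 and 2 were thus on both sides, and the spread between positions stayed within each group. As these arrays grouped by position, the count of 0 does not show that this cultivar lacked a response. By camera 6 lists shifted up and 2 down, none with an estimated correlation, and 0 members of any list passed adjusted over the list alone. These shifts cannot be told apart from the difference of position 4 and position 3 that the layout leaves. The aquaporin list had a median of 0.34 (adjusted p = 3.49e-06, and adjusted p = 0.482 with an estimated correlation), jasmonate 0.28, LEA and dehydrin 0.23, DREB and ERF 0.22, ribosome 0.14 and auxin 0.026, which turned to -0.076 with array weights and to -0.038 and -0.015 without untreated or drought replicate 2. Photosynthesis had a median of -0.21 (adjusted p = 0.000130, and adjusted p = 0.748 with an estimated correlation) and MYB factors -0.22. With array weights the count was 2114.

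In the arrays labelled M PER417-003, again no probe passed (0 higher, 0 lower, with 532 at an unadjusted p under 0.05). Here the untreated arrays lay at positions 3, 4 and 1 and the drought arrays at positions 2, 3 and 4. Positions 3 and 4 were thus on both sides, and this 0 likewise does not show that a response was lacking. The NCED3 probes differed by 3.60 and 4.43 (SE 2.69 and 2.96, adjusted p = 1 for both). No list call held with an estimated correlation, the smallest adjusted p being 0.299. The lists that passed camera upward with the preset correlation were DREB and ERF (median 0.53), jasmonate (0.36), root transport (0.24), WRKY (0.22), aquaporin (0.17), NAC (0.13), osmolyte (0.11) and redox (0.10). Photosynthesis (-0.26, adjusted p = 6.40e-14) and the clock (-0.12) passed downward. All these list shifts cannot be told apart from the difference of position 2 and position 1 that the layout leaves. Some of these directions turned with 1 array left out. Without drought replicate 1 the jasmonate median was -0.037, osmolyte -0.13 and the clock 0.010, and osmolyte was -0.020 without untreated replicate 1 and -0.041 with slide as a fixed block. Adjusted over the list alone, 0 members of any list passed. Without untreated replicate 3 the count of changed probes was 2.

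Averaged over the 3 cultivars, 5 probes rose and 103 fell, 4 and 16 of them at least 2-fold. The kinases CIPK23 and CIPK9, which act with calcium sensors on ion channels, fell by 0.99 (SE 0.19, adjusted p = 0.0324) and by 0.86 (SE 0.16, adjusted p = 0.0324), and the DNAJ co-chaperone fell by 0.71 (SE 0.15, adjusted p = 0.0489). These 3 probes were well above background on all 18 arrays, as were 74 of the 108 called; 25 were not on any array labelled M TAI16 or M PER417-003. CUE1 was among the 25 and passed (adjusted p = 0.0117), but only its M ECU72 bound of 3.72-fold can be given. The 5 rises, named after their values were seen, were the termination factor R_Mes01_009048, the small peptide DVL11 (R_Mes01_021433) and 3 probes with no description (R_Mes01_015276, R_Mes01_010300 and R_Mes01_018940). None of the 5 was well above background on an untreated M ECU72 array. Their M ECU72 bounds were at least 2.37-fold, 1.61-fold, 40.4-fold, 1.69-fold and 2.36-fold in that order, and all but DVL11 and R_Mes01_015276 were not well above background on any array of the other labels. With signals near background counted, the log2 changes of the 5 ran from 1.78 to 7.04 in M ECU72. They ran from -0.077 to 0.942 in M TAI16 and from -0.265 to 0.362 in M PER417-003, so these averages rest mainly on M ECU72. The 2 NCED3 probes, at 5.12 and 4.95, did not pass (adjusted p = 0.162 and 0.203). In the average, 10 lists passed camera upward and 2 downward, none of them with an estimated correlation. The smallest p values were those of aquaporin (0.31, adjusted p = 1.25e-08) and photosynthesis (-0.22, adjusted p = 1.60e-09), while the medians farthest from 0 were those of jasmonate (0.68) and the clock (-0.36). With an estimated correlation the aquaporin and photosynthesis adjusted p values were 0.189 and 0.408. No probe changed in all 3 cultivars (limma, 0 probes in each direction). With 0 probes called in the arrays labelled M TAI16 and M PER417-003, this count could not exceed 0. The average count was 0 with quantile normalization, 0 with slide as a fixed block, 0 with the replicate number as a block and 92 with slide as a random block. It was 692 without M TAI16 untreated replicate 2, and 106, 156 and 97 without M TAI16 drought replicate 2, M ECU72 drought replicate 2 and M PER417-003 drought replicate 1. Leaving out any other array gave 2 to 71.

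Over probes, the drought differences by label correlated between cultivars at r = 0.435 for M TAI16 and M ECU72, 0.449 for M PER417-003 and M ECU72 and 0.439 for M TAI16 and M PER417-003. No arrays are shared between them, and probes are not independent replicates. Once shared positions cancel, the M TAI16 labels leave position 4 against position 3, and the M PER417-003 labels position 2 against position 1. Those position differences correlated with the M ECU72 effect at r = 0.534 and 0.594 and with each other at r = 0.712. The values by label are not separate from these and do not by themselves show alike responses of the cultivars. The difference in drought effect itself passed for 3 probes between M ECU72 and M TAI16. These were a 2OG-Fe(II) oxygenase (R_Mes01_004623, -2.87, adjusted p = 0.0393) and 2 probes with no description (R_Mes01_009004 at 2.92 and R_Mes01_016959 at -1.54). Between M ECU72 and M PER417-003, the pentatricopeptide protein R_Mes01_008820 (2.92, adjusted p = 0.0481), the termination factor R_Mes01_009048 (3.75) and R_Mes01_009004 (2.86) passed. Between M PER417-003 and M TAI16 no probe passed (limma, 0 probes, with 269 at an unadjusted p under 0.05). The termination factor, R_Mes01_009004 and the oxygenase were well above background in only 1 of the 6 groups, and R_Mes01_016959 only in the M ECU72 groups, so the sizes of their differences rest on signals near background. Both counts of 3 became 0 with the replicate number as a block and 0 with slide as a fixed block, and leaving out any 1 M TAI16 array gave 0 for the first. NCED3 and LEA14 are not shown to respond differently between cultivars, nor are the other transcripts named for M ECU72 apart from R_Mes01_008820 and R_Mes01_009048, which passed only against M PER417-003.

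Untreated M ECU72 differed from the untreated arrays labelled M TAI16 in 6829 probes (3774 higher, 3055 lower) and from those labelled M PER417-003 in 7419 (4182 higher, 3237 lower). At 2-fold or more these were 4229 and 4746. The excess of higher probes depended on the processing and on single arrays. Against M TAI16, normexp background gave 3106 higher and 4588 lower, no filter 3973 and 4822, and leaving out M TAI16 untreated replicate 2 gave 2347 and 2428. Against M PER417-003, normexp gave 3385 and 4445, no filter 4388 and 5033, and median scaling 3683 and 3768. Among the named differences, several were lower in M ECU72. A probe for an FG-GAP repeat protein (R_Mes01_000409) was at -10.64 (SE 0.67, adjusted p = 1.51e-07) and one for the peroxisomal malate dehydrogenase PMDH2 (R_Mes01_002676) at -10.39 (SE 1.08, adjusted p = 1.59e-05) against M TAI16, each well above background on 1 of the 3 untreated M ECU72 arrays. A lipid transfer family protein (R_Mes01_012960) was at -9.74 with 2 such arrays. Against M PER417-003 the first 2 were at -10.96 and -11.17, and the meristem factor KNAT1 (R_Mes01_010657) at -9.75 (SE 0.36, adjusted p = 4.63e-10), with 1 such array. Higher in M ECU72 than M TAI16 were a leucine-rich repeat protein (R_Mes01_015404, at least 9.75-fold), a putative inositol-3-phosphate synthase (R_Mes01_009453, at least 8.59-fold) and a CCCH zinc finger protein (R_Mes01_001606, 4.24, well above background on 2 of the 3 M TAI16 arrays). Against M PER417-003 these were TTN5 (5.64, SE 2.15, adjusted p = 0.0494), orf764 (4.99) and the lipid-binding NTMC2T4 (4.57), each well above background on 1 of the 3 M PER417-003 arrays. All M ECU72 arrays were scanned in another session than the rest, so cultivar and scan session cannot be told apart here. Untreated arrays labelled M PER417-003 and M TAI16 differed in 0 probes (limma, 244 at an unadjusted p under 0.05). They lay at positions 3, 4 and 1 and at positions 1, 2 and 3, and the model did not include position. This 0 therefore does not show that the cultivars were alike.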

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

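The tests of the array grouping, of stem share, harvest time, scan session and probe capture were chosen only after the results were seen; the counts over other splits of the arrays were planned.

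The drought effect differed between M ECU72 and M TAI16 in 3 probes and between M ECU72 and M PER417-003 in 3 probes, by a test of the difference itself. Over 100 splits of the arrays, 7 gave at least 3 probes for the first difference (highest other 2020) and 9 for the second (highest other 740), so chance was not excluded for either. For M PER417-003 against M TAI16 all 100 splits gave at least the 0 probes called, with a highest other of 3905. Splits that call far more probes than the labels point to a structure of the arrays that the labels do not describe.

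The 12 arrays labelled M TAI16 and M PER417-003 correlated by slide position and not by labelled group. In label order they run through positions 1 to 4 of slides 4, 5 and 6, so each labelled group mixes 3 positions, while each M ECU72 group lies at 1. The labelled cultivar and treatment were argued against as the source of this grouping, since a share of 0.801 of all partitions correlated as highly as the labelled groups. That share is part of the pattern itself, so it counts against the labels as deposited and speaks for no other source. A technical effect of position was not decided. Position 4 minus position 2 in these arrays correlated with the M ECU72 drought effect, also position 4 minus position 2, at r of -0.19 over probes. That M ECU72 difference also holds the drought treatment and came from other slides, scanned in another session. This r therefore cannot tell whether position acted on slides 4, 5 and 6. Files paired with the wrong sample labels may explain it, but no test decided this: the share of 6.49e-05 of partitions correlating as highly as the positions restates the grouping, and any effect tied to position would give it too. With groups made of the positions, position 2 minus position 1 differed in 3228 probes and position 4 minus position 3 in 1128, within 1128 to 7977 for all pairs of positions. The jasmonate, LEA and dehydrin and DREB and ERF lists shifted up in both with an estimated correlation (adjusted p = 0.0209, 0.0209 and 0.0130, and 0.0185, 0.00676 and 0.00676). These 2 differences correlated with the M ECU72 drought effect at r of 0.594 and 0.534 and with each other at 0.712. For the other pairs of positions the r with that effect ran from -0.450 to 0.303. The groups and these pairs were chosen from the grouping itself, which narrows their spread, so these values do not decide it either. Which sample belongs to which file is not known, so no condition was assigned to any position.

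In M ECU72, 9 lists shifted up and 2 down after drought by camera with a preset correlation, and 0 of these held with an estimated correlation. A larger share of stem in the drought samples could contribute, with a xylem median of 0.37. Another time of day at harvest could too, with a clock median of -0.47, but a median over clock genes does not tell a later hour from an earlier one. The estimated correlation gave these lists adjusted p = 0.478 and 0.542, so both stay open beside the labelled treatment. Array position also stays open, since in M ECU72 it cannot be told apart from the label. The labels give no harvest times and no stem share.

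The M ECU72 arrays differed from the other 12 arrays in 6340 probes upward and 4818 downward. The scan session cannot be told apart from the cultivar, since 0 arrays outside M ECU72 shared its session. Transcripts that the probes do not capture in M ECU72 may contribute, as 84.4% of the 199 called probes with a 16-fold or larger difference were lower in M ECU72, 168 against 31. A cultivar difference in expression stays open and was not tested apart from these.

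For groups of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The labels gave 195 probes for the M ECU72 drought effect, with 1 of 10 splits reaching that and a highest other of 5. They gave 6829 and 7419 for untreated M ECU72 against M TAI16 and M PER417-003, each reached by 1 of 10 splits with a highest other of 0. The drought effects in M TAI16 and M PER417-003 had 0 probes, reached by 10 of 10 splits, with a highest other of 1472 and 0. The split with 1472 exchanged M TAI16 untreated replicate 2 and drought replicate 1 and put both arrays at position 2 in 1 group. Untreated M PER417-003 against M TAI16 had 0 probes, reached by 10 of 10 splits, with a highest other of 42. For the average drought effect 3 of 100 splits gave at least the 108 probes of the labels, which excludes chance at 0.05 only for arrays exchanged freely within a cultivar. The splits ignored slide and position, another gave 813, and the count was 0 with the replicate number as a block and 0 with slide as a fixed block, so a structure of the arrays stays open. For probes changed in all 3 cultivars 100 of 100 splits gave at least the 0 called.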

How the results depend on the processing

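The spread from array positions, alone or with the replicate block, and the replicate block on only the groups compared were chosen only after the data were seen. The cause was not tested for the changes below.

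The drought effect in M ECU72 (195 probes) gave 736 with normexp background, 308 with no filter, 89 with probes above background on all 18 arrays, 3240 with array weights, 661 on only the groups compared, 60 with slide as a fixed block and 0 with the replicate block. It gave 2844 with the spread from array positions, 3294 with that and the replicate block, and 0 on only the groups compared with the replicate block. Quantile normalization gave 63 higher and 112 lower against 47 and 148. Leaving out an array gave 36 to 295. As for pairing, arrays of the same number in M ECU72 had deviations from their group means correlated at 0.0074, -0.309 and -0.128, so the numbers were not taken to pair the samples.

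The average drought effect (108) gave 0 with quantile normalization, 47 with median scaling, 296 with normexp, 68 with probes above background on all 18 arrays, 69 with a trended robust prior, 2261 with array weights, 20 at 2-fold, 0 with the replicate block, 0 with slide fixed, and 2 to 692 leaving out an array.

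The difference M ECU72 minus M TAI16 (3) gave 0 with quantile, median and normexp settings, all 18 arrays above background, the trended prior, only the groups compared, the replicate block and slide fixed, 7 with no filter, 1120 with array weights, and 0 to 11 leaving out an array. M ECU72 minus M PER417-003 (3) gave 0 with quantile normalization, the deposited value table, the trended prior, only the groups compared, the replicate block and slide fixed, 9 with no filter, 1 with all 18 arrays above background, 13 with array weights, and 0 to 12 leaving out an array. M PER417-003 minus M TAI16 (0) gave 2 with array weights and 0 to 1 leaving out an array.

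The drought effect in M TAI16 (0) gave 1 with no filter, 2114 with array weights and 0 to 0 leaving out an array; in M PER417-003 (0) leaving out an array gave 0 to 2. Untreated M ECU72 against M TAI16 (6829) gave 4549 on only the groups compared, 4229 at 2-fold and 4775 to 6696 leaving out an array, and against M PER417-003 (7419) 4746 at 2-fold and 5649 to 6550. Slide as a fixed block could not be estimated for these. Untreated M PER417-003 against M TAI16 (0) gave 1 with no filter, 1566 with array weights and 5 with slide fixed. Probes changed in all 3 cultivars stayed at 0 in every setting run.

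Some list medians changed sign. Auxin in M TAI16 had -0.0762 with array weights and -0.0385 to 0.146 leaving out an array. In M PER417-003, leaving out an array gave -0.269 to 0.448 for ABA metabolism, -0.426 to 0.0101 for the clock, -0.0983 to 0.0259 for heat shock, -0.0371 to 0.990 for jasmonate and -0.126 to 0.492 for osmolyte, which had -0.0409 with slide fixed. Meristem in M ECU72 gave -0.276 to 0.0469. With arrays left out, the values farthest from the main direction came without M TAI16 untreated replicate 2 (auxin), M PER417-003 drought replicate 1 (clock, jasmonate, osmolyte), drought replicate 2 (heat shock) and untreated replicate 2 (ABA metabolism), and M ECU72 drought replicate 1 (meristem). No named gene changed sign in a setting where it passed there or in the main fit. In 21 settings of named genes the sign did change, with no call in either fit. Averaging several probes of a contig did not apply, and camera with slide as a random block gave no value. Probes not well above background limit the folds to lower bounds.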

Other observations

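The comparisons of position differences were chosen only after the data were seen. Over the 18646 probes, position 2 minus position 1 in the 12 arrays labelled M TAI16 and M PER417-003 correlated with the M ECU72 drought effect at r = 0.594, and position 4 minus position 3 at r = 0.534. These position differences correlated with each other at r = 0.712. The correlations with the M ECU72 drought effect were -0.0636 for position 3 minus position 1, 0.303 for position 4 minus position 1 and -0.450 for position 3 minus position 2. By label, the M TAI16 and M PER417-003 drought differences correlated with it at 0.435 and 0.449. These are not separate values, since the labels leave position 4 against position 3 and position 2 against position 1 once shared positions cancel. Probes are not independent replicates.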
